A study of Mus musculus with 42 samples.

How the data were processed

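Total RNA of 42 brain fractions from 5 male R6/2 mice was measured on 1 Agilent mouse array each, and replicate numbers in the labels are positions along a plane, not repeats. Per the labels' protocols, RNA was extracted with a magnetic-bead total RNA kit and labelled in 1 colour (Cy3) with a low-input kit. The deposited text files hold intensity values per spot: per the file headers, Agilent Feature Extraction 10.5.1.1 (39 arrays) or 10.10.1.1 (3 arrays) gave the processed signal, corrected for background and, on 1 array, for a spatial trend, beside the median pixel brightness of the spot and of its local background. The deposited series table holds log2 values of 40635 probes, which equal the log2 of the processed signal minus the 75th percentile of the array, within 0.0088 on every array. Array medians of those values run from −2.01 to −1.30.

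Values were computed from the spot files. Control spots and spots marked as outliers by the software (84 to 217 per array) were dropped, log2 values of the processed signal were averaged over spots of 1 probe and scaled by subtracting the 75th percentile of each array. Left out were 171 probes whose every spot was an outlier on some array. Of the 55681 probes, 27235 carried 1 gene symbol and 28446 none, by matching the files' accessions to a RefSeq gene table. Probes well above background, as marked by the software, on at least 3 of 42 arrays were tested, which gave 40516 probes, 22545 of them with a symbol, for 17161 genes. Each fraction was measured once, so precision rests on the spread around fitted curves.

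Position was tested in 1 limma fit of all 42 arrays with 17 coefficients and 25 residual degrees of freedom. Each series had its own intercept and curve, cubic for the coronal series, quadratic for the horizontal and oblique series, and for the sagittal series a signed linear term plus linear and squared distance from the middle of the fraction numbers. Directions come from the orthogonal linear term. P-values were adjusted by Benjamini-Hochberg over all probes, with a threshold of 0.05. Lists of marker genes (26) were written before the data were examined and tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation, on 1 probe per gene. Coherence was compared with 10000 random lists matched in 20 bins of mean expression, by a two-sided exact sign-flip permutation over mice. Co-variation with the striatum list used Fisher's z, weighted by the number of fractions minus 3, tested over mice with limma, the list mean leaving out a member tested against it, and a correlation of at least 0.7 in every mouse. Genes that set a mouse apart passed a limma contrast of that mouse against the mean of the other 4 and lay at least 1 log2 beyond every fraction of the others.

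Fold differences are between a gene's highest and lowest fraction. Where the lower end was not well above background, the fold is given as at least N, from the bright fraction over the higher of that array's lowest well-above-background signal and the probe's own signal. Named genes were chosen by a rule written in advance: the 5 largest slopes per direction past the threshold, up to 4 members of each list by size of slope whether or not they passed, the 5 smallest adjusted p for the oblique difference, the 10 highest co-varying genes outside the striatum list and up to 5 genes per mouse. Genes without a proper name were counted, not named, and some genes that the rule selects are not reported here. Immediate early genes were singled out between mice after their values were seen.

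Alternatives were normexp background correction (offset 50), quantile normalization, the deposited log2 table, no filter, probes well above background on all 42 arrays (20865), a fit of the tested series alone, a polynomial 1 degree lower, 1 probe per gene, slides as a random block (correlation 0.159), no second scanner, no end fractions, reversed right oblique numbers, Spearman correlation and other limits. Normexp was planned on mean pixel brightness, which the files do not hold, and used the median instead. Leaving out the 3 arrays of lowest signal, leaving out 2 inner fractions per series, and a sagittal middle at fraction 6, where striatal and ependymal profiles centred, were chosen after the data were seen. Orders of the fractions were permuted 100 times per test.

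The fits were tested on simulated data. A coronal slope was recovered in 67% of changed probes at 0.2 log2 per fraction and 97% at 0.4, a mouse difference in 41% at 2 log2 and 90% at 4, and co-variation in 62% and 93% at a profile size of 1 and 2. Of unchanged probes 7 were called in the coronal test and 0 in the others. The simulated noise was independent between arrays, and in the mouse test unchanged probes had the same level in every mouse. Low false counts were thus partly built in and do not measure those of the real arrays. Tools were R 4.3.3, limma 3.58.1, version 1.17.8 of the data.table package, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.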

Results

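The series maps gene expression through the whole brain of the R6/2 mouse, a model of Huntington disease that carries the start of the human huntingtin gene with an expanded CAG repeat. Brains of 5 male mice aged 5 weeks were each sectioned in 1 plane into slabs of 1 mm, and the total RNA of each slab, called a fraction, was measured on 1 one-colour Agilent array. Mouse 1 gave 12 coronal fractions, mouse 2 gave 6 horizontal fractions, mouse 3 gave 7 left oblique fractions, mouse 4 gave 7 right oblique fractions and mouse 5 gave 10 sagittal fractions. The labels number the fractions of a plane in order but do not say at which pole of the brain the numbers start, so positions are given as fraction numbers. Each position was measured once, and plane and mouse cannot be told apart. P-values come from how closely the fractions followed a smooth curve and describe these 5 brains only. Wild-type brains were not analysed here.

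Signal differed between arrays. The 75th percentile of the processed signal lay between 111 and 537, and the share of probes well above background between 47.6% and 68.8%. The lowest 75th percentiles belonged to fraction 1 of the horizontal series (111), fraction 1 of the right oblique series (121) and fraction 1 of the sagittal series (143). No spot was saturated. Of 55681 probes, 40516 were well above background on at least 3 of the 42 arrays, and they covered 17161 named genes.

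The coronal series showed where along the brain each gene was expressed. Hindbrain and cerebellar genes were high in the low-numbered fractions and fell toward fraction 12. Hox genes, which set the identity of hindbrain and spinal cord segments, were highest in fraction 1. Hoxc4 was at least 289-fold higher there than in its lowest fraction (slope −0.75 ± 0.133 log2 per fraction, SE), Hoxb5 at least 153-fold (−0.69 ± 0.122) and Hoxb4 at least 98.6-fold (−0.70 ± 0.12). Gabra6, the GABA receptor subunit of cerebellar granule cells, was 128-fold higher in fraction 3 than in fraction 10 (−0.70 ± 0.0609). Cbln1, a synaptic organiser that granule cells secrete, was 59.8-fold and Fat2, a granule cell cadherin, 41.9-fold higher in fraction 3 than in fraction 9. The Purkinje cell genes Pcp2 and Ppp1r17 fell by 0.64 and 0.65 log2 per fraction, with a 127-fold range for Pcp2. Bcl2l15 fell as well (−0.72 ± 0.075) and was at least 36.1-fold higher in fraction 3 than in fraction 10.

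Of 12 hindbrain genes measured, 11 fell and 1 did not pass the test, and 12 were called when adjusted over the list alone (camera adjusted p = 3.04e-07, adjusted p = 0.305 with an estimated correlation). Of 9 granule cell genes, 8 fell (8 adjusted over the list alone, camera adjusted p = 5.03e-07, adjusted p = 0.305 with an estimated correlation). All 7 Purkinje cell genes fell (7 adjusted over the list alone, camera adjusted p = 8.7e-08, adjusted p = 0.305 with an estimated correlation). The mean of the hindbrain list stood 4.36 ± 1.18 log2 (SD of 12 genes) above its series mean in fraction 1, where 10 of the 12 genes peaked.

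Genes of the olfactory bulb, striatum and cerebral cortex ran the other way. Dlx2 and Dlx1, homeobox genes of inhibitory neurons, were highest in fraction 12, at least 108- and 81.0-fold above their lowest fraction, and rose by 0.85 and 0.69 log2 per fraction. Kcnv1, a potassium channel subunit, rose by 0.62 ± 0.0579 log2 per fraction. In the olfactory bulb list 9 of 10 genes rose (9 adjusted over the list alone, camera adjusted p = 1.4e-07, adjusted p = 0.305 with an estimated correlation) and all 10 peaked in fraction 12, among them Sp8 (at least 131-fold) and Cdhr1 (130-fold).

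Striatal genes peaked in fraction 9. Adora2a, the adenosine receptor of indirect pathway neurons, was 42.6-fold higher in that fraction than in fraction 5 (0.36 ± 0.073), and Drd1, the dopamine receptor of direct pathway neurons, was at least 34.8-fold higher than in fraction 2 (0.49 ± 0.0391). Of 20 striatal genes 15 rose, 1 fell and 4 did not pass, with 17 called when adjusted over the list alone (camera adjusted p = 1.34e-08, adjusted p = 0.305 with an estimated correlation), and 19 of the 20 peaked in fraction 9. In the cerebral cortex list 7 of 12 rose and 1 fell (10 adjusted over the list alone, camera adjusted p = 3.52e-05, adjusted p = 0.305 with an estimated correlation). Tbr1, a transcription factor of cortical projection neurons, was 62.0-fold higher in fraction 11 than in fraction 1, and Emx1 at least 29.2-fold above its lowest fraction.

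**Figure D1:**
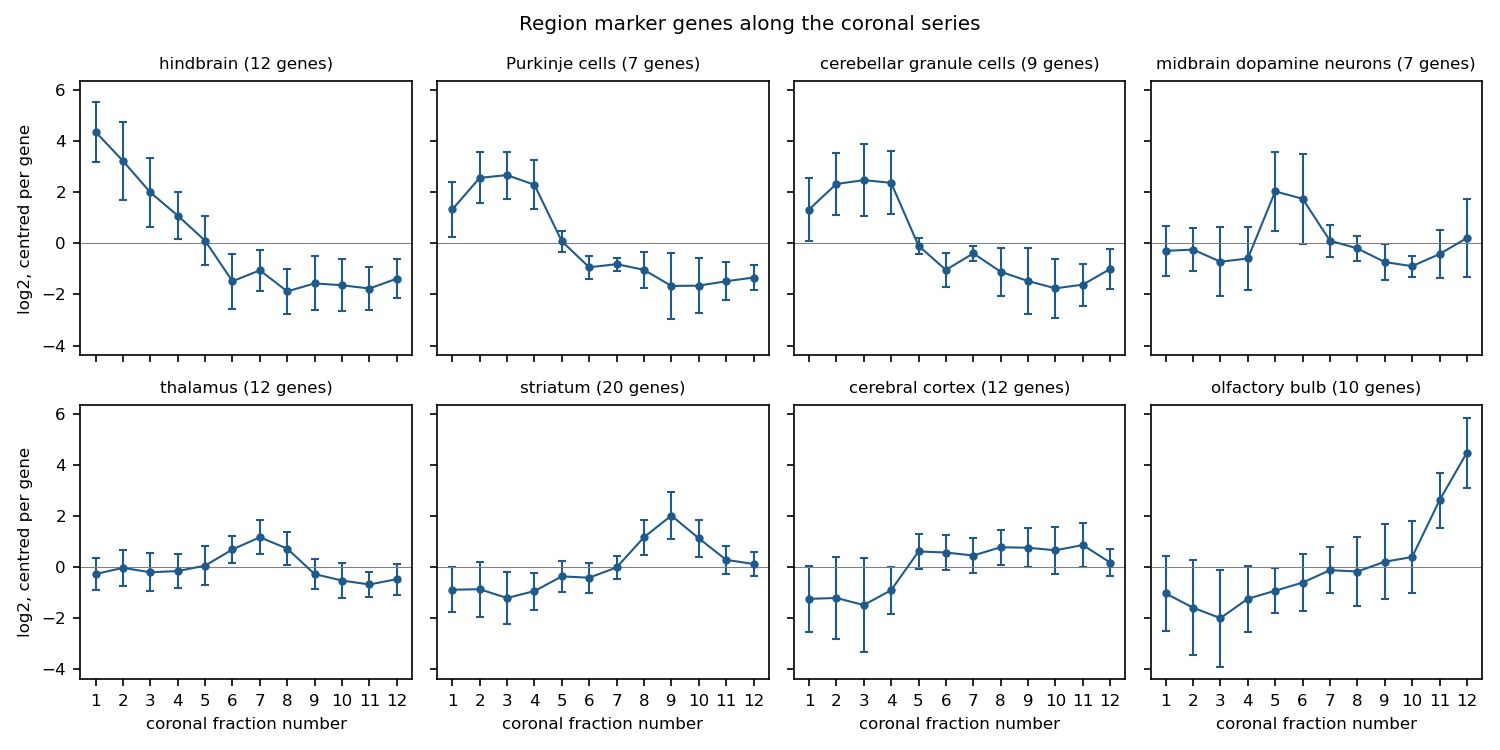
Mean of 8 gene lists in each of the 12 coronal fractions of mouse 1; the x axis is the fraction number, the y axis log2 signal centred per gene on the series mean, and bars are the SD of the list's genes. The hindbrain list is highest in fraction 1 (4.36), the Purkinje cell list in fraction 3 (2.67), the dopamine neuron list in fraction 5 (2.03), the thalamus list in fraction 7 (1.17), the striatum list in fraction 9 (2.01) and the olfactory bulb list in fraction 12 (4.48).

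Genes of regions between these poles peaked in the middle fractions, so most had little slope. Slc6a3, the dopamine transporter, was at least 135-fold higher in fraction 5 than in fraction 3 (slope adjusted p = 0.641), and Slc6a4, the serotonin transporter, was at least 15.7-fold higher in fraction 5 than in fraction 9 (slope −0.31 ± 0.107). Aldh1a1 fell (−0.27 ± 0.0193) and Slc18a2, the vesicular monoamine transporter, fell from a peak in fraction 5 (−0.17 ± 0.0557). The hypothalamic peptide genes Avp (vasopressin), Pmch (melanin-concentrating hormone) and Hcrt (orexin) peaked in fraction 7, at least 472-, 291- and 142-fold above their lowest fraction, and Oxt (oxytocin) in fraction 8 (248-fold). Only Avp passed the slope test among these 4 (adjusted p = 0.02). Of 11 hypothalamic genes 1 rose (1 adjusted over the list alone, camera adjusted p = 0.325), of 7 dopamine neuron genes 3 fell (4, 0.45), of 5 serotonin neuron genes 3 fell (3, 0.257), of 12 thalamic genes 2 fell (2, 0.532), and of 10 hippocampal genes 3 rose and 2 fell (6, 0.845), the values in brackets being the same 2 quantities. Slc17a6, the glutamate transporter of thalamic and other subcortical neurons, fell by 0.20 log2 per fraction, and the hippocampal gene Spink8 rose (0.32 ± 0.0727) with a peak in fraction 6.

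Glial genes also followed the axis, by smaller amounts. Most myelin genes fell: Mag was 7.91-fold and Trf 4.92-fold higher in fraction 3 than in fraction 12, and 8 of 13 oligodendrocyte genes fell (12 adjusted over the list alone, camera adjusted p = 5.89e-05, adjusted p = 0.495 with an estimated correlation). Aqp4, the water channel of astrocytes, was 4.62-fold higher in fraction 3 than in fraction 10, and 7 of 10 astrocyte genes fell while 1 rose (9 adjusted over the list alone, camera adjusted p = 0.00396, adjusted p = 0.415 with an estimated correlation). Microglial genes rose in 11 of 12 cases (11 adjusted over the list alone, camera adjusted p = 1.34e-08, adjusted p = 0.305 with an estimated correlation), including Aif1 (4.89-fold, highest in fraction 11) and the purine receptor P2ry12 (4.60-fold, highest in fraction 10). Immediate early genes, which neuronal activity induces within minutes, rose in 8 of 10 cases and fell in 2 (10 adjusted over the list alone, camera adjusted p = 1.49e-05, adjusted p = 0.305 with an estimated correlation), with 8.80-fold for Egr1, 9.01-fold for Fosb and 8.50-fold for Npas4.

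The remaining lists were not called along the coronal axis. Of 8 endothelial genes 1 rose and 3 fell (5 adjusted over the list alone, camera adjusted p = 0.225). The choroid plexus list had 1 of 11 lower (1, 0.289), although 9 of the 11 peaked in fraction 3 and Otx2 fell 11.1-fold from there. Ependyma had 0 of 6 (0, 0.826, by limma, no list member passed), meninges 1 of 8 lower (0, 0.583), blood 2 of 5 lower (5, 0.0979), pituitary 0 of 6 (0, 0.537) and skeletal muscle 1 higher and 1 lower of 6 (3, 0.8). Among 4 genes of GABA neurons 2 rose and 1 fell (3, 0.79). Of 12 huntingtin partners 1 rose and 2 fell (5, 0.583), the lower ones being Zdhhc17, a palmitoyltransferase of huntingtin, and Rest, a repressor of neuronal genes, both by 0.07 log2 per fraction. Of 9 polyglutamine disease genes Cacna1a fell and Atxn1 rose (2, 0.819), with a median slope of −0.00184 and a mean of −0.000482 while the test pointed up. Of 15 respiratory chain genes 1 fell (1, 0.289). Htt itself is in both of the preceding disease lists.

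In limma's fit 12937 of 40516 probes changed with coronal position, 6758 of them higher toward fraction 12, and 10374 had a linear slope, 5212 up and 5162 down. Position counts move with the processing: normexp background correction called 24328 probes, 15304 of them higher, and a fit of the coronal arrays alone 6459, while the slope count fell to 5960 with slides as a random block.

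The horizontal series divided the brain along the axis across its horizontal planes. Several genes with a large rise were highest in fraction 6. Lhx8, a homeobox gene of cholinergic neurons, was at least 23.1-fold (slope 1.15 ± 0.319 log2 per fraction), Isl1 at least 9.25-fold (0.90 ± 0.22), Arhgap36 26.7-fold (0.94 ± 0.194) and Baiap3 at least 9.44-fold (0.80 ± 0.114) above their lowest fraction. Cpa6, a carboxypeptidase, was at least 15.9-fold higher there (0.90 ± 0.254). Avp and Pmch reached at least 644- and 344-fold in fraction 6 but did not pass the slope test (adjusted p = 0.0951 and 0.125). Of 20 striatal genes 6 rose, with Tac1, the substance P precursor, at 7.64-fold, Rgs9 at 7.81-fold and Drd1 at 4.91-fold. All 4 genes of GABA neurons rose, among them Gad2, which makes GABA (4.45-fold, 0.36 ± 0.0695), and Slc32a1, which loads it into vesicles (3.30-fold). Of 7 Purkinje cell genes 3 fell, Pcp2 by 11.8-fold from fraction 1 to fraction 5 (−0.74 ± 0.127) and Ppp1r17 by 5.88-fold.

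The horizontal slope was called for 9 lists. Striatal genes rose in 6 of 20 cases (10 adjusted over the list alone, camera adjusted p = 0.000407, adjusted p = 0.679 with an estimated correlation) and GABA neuron genes in 4 of 4 (4 adjusted over the list alone, camera adjusted p = 0.00782, adjusted p = 0.416 with an estimated correlation). Hindbrain genes rose in 2 of 12 cases (8 adjusted over the list alone, camera adjusted p = 0.0301, adjusted p = 0.779 with an estimated correlation), including Hoxb4, at least 15.8-fold higher in fraction 4 than in fraction 2. The myelin genes Mag (5.23-fold), Trf and Ugt8a were the 3 of 13 oligodendrocyte genes that rose (6 adjusted over the list alone, camera adjusted p = 0.0301, adjusted p = 0.779 with an estimated correlation). Among 12 huntingtin partners Hap1, which binds huntingtin, Zdhhc17 and Hip1 rose by 0.32, 0.20 and 0.17 log2 per fraction (4 adjusted over the list alone, camera adjusted p = 0.0364, adjusted p = 0.68 with an estimated correlation), while Htt itself did not pass (adjusted p = 0.0865). Purkinje cell genes fell in 3 of 7 cases (4 adjusted over the list alone, camera adjusted p = 0.000202, adjusted p = 0.442 with an estimated correlation) and granule cell genes in 1 of 9 (1 adjusted over the list alone, camera adjusted p = 0.0179, adjusted p = 0.71 with an estimated correlation). Of 10 immediate early genes Arc and Npas4 fell (2 adjusted over the list alone, camera adjusted p = 0.03, adjusted p = 0.68 with an estimated correlation). Of 15 respiratory chain genes Cox6a1 and Cox4i1, subunits of cytochrome oxidase, fell by 0.19 log2 per fraction each (3 adjusted over the list alone, camera adjusted p = 0.05, adjusted p = 0.779 with an estimated correlation), and this list's median of −0.04 turned to 0.04 with quantile normalization (adjusted p = 0.34), where Cox6a1 was at 0.01, to 0.03 with normexp (0.363) and to 0.03 without the 3 arrays of lowest signal (0.109).

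Of the other lists, the thalamus had 4 of 12 genes higher (5 adjusted over the list alone, camera adjusted p = 0.257), led by Slitrk6, at least 22.5-fold higher in fraction 4 than in fraction 1. The hypothalamus had 2 of 11 higher (2, 0.128), dopamine neurons 1 of 7, Ddc (1, 0.359), microglia 1 of 12, Cx3cr1 (1, 0.644), and the choroid plexus 1 of 11, Aqp1 (1, 0.257). The hippocampus had 2 higher and 1 lower of 10 (3, 0.999), with a median slope of 0.10, a mean of −0.00241 and a test that pointed down. Endothelial cells had 1 of 8 higher (1, 0.927), with a median of −0.00778 against a mean of 0.02, and ependyma 1 of 6 higher, Foxj1, a regulator of motile cilia (3, 0.207). Polyglutamine disease genes had Atxn2 higher and Atxn7 lower of 9 (4, 0.644). By limma 0 members passed in the cortex (0 adjusted over the list alone, camera adjusted p = 0.27), olfactory bulb (0, 0.135), serotonin neuron (0, 0.819), astrocyte (0, 0.532), meninges (0, 0.27), blood (0, 0.188), pituitary (0, 0.845) and skeletal muscle (1, 0.202) lists. The serotonin and pituitary tests pointed down against median slopes of 0.01 and 0.10.

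Genes that fell most were an olfactory receptor gene, Olfr557 (−1.25 ± 0.195, at least 104-fold), the nuclear receptor gene Nr0b2, Skint4, the vomeronasal receptor gene Vmn1r157 and Mrgpra3. All 5 were highest in fraction 1, the array of lowest signal, where probes that were never well above background also stood 1.88 log2 higher than on the other horizontal arrays. In all, 13459 probes changed with horizontal position in limma (7171 higher) and 4964 had a slope (3252 higher). The slopes depended on the model. A fit of the horizontal series alone called 0 in limma (14204 unadjusted), which ends every slope call named above, and a polynomial 1 degree lower called 345 for position and 345 for the slope. Without fraction 1 these counts were 387 and 125, the slope count was 1803 without fraction 5 and 12243 without fraction 6, and the splits were 9542 of 14770 and 4771 of 6247 higher with quantile normalization and 7019 of 28010 and 4446 of 21182 with normexp. List calls also ended: hindbrain, granule cells and immediate early genes with normexp (0.585, 0.226 and 0.199), hindbrain without the second scanner (0.0714), and oligodendrocytes and huntingtin partners with quantile normalization (0.0878 and 0.0964) and with probes well above background on all 42 arrays (0.0883 and 0.114). So did those of granule cells, immediate early genes and the respiratory chain with no filter (0.078, 0.121 and 0.219), the respiratory chain with the deposited table (0.0501), with the sagittal middle at fraction 6 (0.0503) and without the end fractions (0.76), huntingtin partners without the end fractions (0.0863), and GABA neurons, oligodendrocytes and huntingtin partners without the 3 arrays of lowest signal (0.199, 0.717 and 0.717).

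The sagittal series ran from side to side, and its fractions were ordered by distance from the middle of their numbers, between fractions 5 and 6. The midline of the brain need not lie there. The mean of striatal genes peaked in fractions 4 and 8, and that of ependymal genes in fraction 6 (1.31 ± 0.678 log2 above the series mean, SD of 6 genes). A middle at fraction 6 was therefore also tried, after these profiles were seen. Many hindbrain, dopamine neuron and thalamic genes fell with distance. The Hox gene Hoxb4 fell by 1.14 ± 0.32 log2 per fraction. Irx2 (at least 6.24-fold higher in fraction 6 than in fraction 1), Hoxc4 (−0.99, but an adjusted p of 0.0579 with the middle at fraction 6) and Pou4f2 (−0.98) followed. Th, which makes the dopamine precursor, was 10.6-fold higher in fraction 6 than in fraction 2 (−0.59 ± 0.196), Slc18a2 9.73-fold higher than in fraction 3 and Slc17a6 7.49-fold higher than in fraction 2 (−0.66 ± 0.116). Genes that rose most outward were Snora74a, a small nucleolar RNA (0.83 ± 0.128, 24.9-fold), Aste1, Plb1, a phospholipase (12.5-fold), Msln, mesothelin (0.74 ± 0.0528, 13.3-fold), and Vmn1r68. Emx1, a transcription factor of the cortex, was 5.42-fold higher in fraction 1 than in fraction 6 (0.57 ± 0.134).

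Most myelin genes fell toward the edges and most microglial genes rose. Ugt8a, which makes a myelin lipid, was 4.51-fold and Mag 4.15-fold higher in fraction 4 than in fraction 1, and 11 of 13 oligodendrocyte genes fell (12 adjusted over the list alone, camera adjusted p = 8.7e-08, adjusted p = 0.305 with an estimated correlation). Aif1 was 4.77-fold higher in fraction 1 than in fraction 5, and with Trem2, C1qb and C1qa it was among 9 of 12 microglial genes that rose (11 adjusted over the list alone, camera adjusted p = 3.34e-07, adjusted p = 0.305 with an estimated correlation). Of 5 blood genes 4 rose, all haemoglobin genes (5 adjusted over the list alone, camera adjusted p = 0.0291, adjusted p = 0.68 with an estimated correlation). Respiratory chain genes rose in 8 of 15 cases, led by Cox4i1 (0.33 ± 0.049) and Cox6a1 (0.30 ± 0.0456) (10 adjusted over the list alone, camera adjusted p = 0.000439, adjusted p = 0.679 with an estimated correlation), but the list's median of 0.11 turned to −0.04 with quantile normalization (adjusted p = 0.138), where Ndufb8 was at −0.02. These 3 lists peaked in fraction 1, the sagittal array of lowest signal, on which probes never well above background stood 1.18 log2 higher than on the other sagittal arrays.

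All 4 genes of GABA neurons fell, led by Gad2 (−0.39 ± 0.065) (4 adjusted over the list alone, camera adjusted p = 0.00109, adjusted p = 0.305 with an estimated correlation). Thalamic genes fell in 7 of 12 cases (8 adjusted over the list alone, camera adjusted p = 0.00233, adjusted p = 0.639 with an estimated correlation), hindbrain genes in 8 of 12 (9 adjusted over the list alone, camera adjusted p = 0.00143, adjusted p = 0.679 with an estimated correlation) and dopamine neuron genes in 4 of 7 (4 adjusted over the list alone, camera adjusted p = 0.0264, adjusted p = 0.679 with an estimated correlation). Olfactory bulb genes fell in 4 of 10 cases, including Sp8, Eomes and Cdhr1 (4 adjusted over the list alone, camera adjusted p = 0.0264, adjusted p = 0.779 with an estimated correlation). Granule cell genes fell in 5 of 9 cases and rose in 1, with Zic2 at −0.52 and Cbln1 at −0.42 (8 adjusted over the list alone, camera adjusted p = 0.0307, adjusted p = 0.779 with an estimated correlation). Among 12 huntingtin partners Ppargc1a, a regulator of mitochondrial genes (−0.28 ± 0.0394), Hip1, Zdhhc17 and Rest fell (4 adjusted over the list alone, camera adjusted p = 0.0291, adjusted p = 0.679 with an estimated correlation).

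The other lists were not called with distance. Of 20 striatal genes 0 passed by limma (0 adjusted over the list alone, camera adjusted p = 0.819); their mean profile had peaks in fractions 4 and 8. The cortex had 3 of 12 higher and 1 lower (5, 0.202), the hippocampus 1 higher and 3 lower of 10, Prox1, Zbtb20 and C1ql2 (5, 0.363), the last of which was at 0.02 with normexp. Lower were 3 of 11 hypothalamic genes (3, 0.0955), 2 of 5 serotonin neuron genes (2, 0.344), 2 of 7 Purkinje cell genes (2, 0.0968), 3 of 10 astrocyte genes (3, 0.239), 1 of 11 choroid plexus genes, Otx2 (1, 0.136), 2 of 6 ependymal genes, Foxj1 and Tmem212 (2, 0.214), and 1 of 8 meningeal genes, Igf2 (1, 0.891, median 0.02, test down). Endothelial genes had 2 higher and 1 lower of 8 (4, 0.425), skeletal muscle 1 of 6 higher, Tnni2 (1, 0.594), and immediate early genes 1 of 10 higher, Npas4 (0, 0.286). By limma 0 of 6 pituitary genes (0, 0.975, median 0.00496, mean −0.09) and 0 of 9 polyglutamine disease genes (0, 0.27) passed, with Htt at an adjusted p of 0.405.

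In limma's fit 8703 probes changed with distance (4716 higher) and 9448 had a linear slope (5152 higher). With the middle at fraction 6 they were 9168 and 9840, 8395 and 9352 of them shared. All 11 lists called with distance stayed called there. Without fraction 1 the counts were 3081 and 4586 and without fraction 10 they were 5470 and 6099, and the higher calls were 3979 of 9489 and 4176 of 10052 with quantile normalization and 13176 of 16536 and 16663 of 20499 with normexp. List calls ended for granule cells with quantile normalization, without the end fractions, without the 3 arrays of lowest signal and with probes well above background on all 42 arrays (0.0913, 0.981, 0.264 and 0.0767). They ended for blood with normexp, without the end fractions, without the 3 arrays and with no filter (0.132, 0.36, 0.147 and 0.0579). They also ended for hindbrain and the respiratory chain with normexp (0.0732 and 0.227), for huntingtin partners without the end fractions (0.062) and for olfactory bulb and dopamine neurons with probes well above background on all 42 arrays (0.147 and 0.0673).

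The sagittal series also allowed a comparison of its low-numbered with its high-numbered side. Its result hung on where the middle was put. With the middle between fractions 5 and 6, 41 of 40516 probes had such a slope in limma, 19 higher and 22 lower (5976 at an unadjusted p under 0.05). With the middle at fraction 6 limma called 0 (1302 unadjusted). The count was also 1 with slides as a random block, 2 with quantile normalization and 0 in a fit of the series alone (7012 unadjusted), all by limma. Normexp gave 766 higher of 13938. Without fraction 1, 2, 3, 6, 7, 8, 9 and 10, in that order, it was 3, 156, 645, 12, 520, 20, 7 and 2. With the middle between fractions 5 and 6 only, Ssc4d rose across the series (0.29 ± 0.0599, 42.2-fold between fractions 10 and 4), as did Scai (0.27 ± 0.0462), Zfp773, Zfp971 and Dusp18, and the hormone gene Sct (−0.18 ± 0.0355), Mospd2, Cracr2b, Cox8a and Fkbp1a fell. None of these 10 genes passed with the middle at fraction 6, with slides as a random block, with quantile normalization or in the fit of the series alone. Zfp773, Zfp971 and Dusp18 had slopes of −0.05, −0.05 and −0.03 with normexp. By limma 0 members of the 26 lists passed over all probes, while adjusted over the list alone 4 of 8 endothelial, 2 of 4 GABA neuron, 1 of 12 huntingtin partner and 5 of 15 respiratory chain genes passed. Fractions at equal distance by number from the middle between fractions 5 and 6 correlated across probes at a mean r of 0.05 ± 0.195 (SD, 5 pairs), against −0.16 ± 0.241 over 32 other pairs, which the exact one-sided permutation over 120 pairings did not separate (p = 0.133). With probes well above background on all 42 arrays the mean r was 0.33 (exact permutation p = 0.0333). With the 4 pairs around fraction 6 it was 0.11 (24 pairings, exact permutation p = 0.125). Since the pairs need not be mirror images of the brain, these values do not measure left-right symmetry. Correlations across probes describe arrays, since probes are not independent replicates.

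The oblique series came from different mice, 1 cut in each plane. Peaks were taken from the mean of each list, so single genes could peak elsewhere. On the left 3 of 12 cortical and 2 of 10 hippocampal genes peaked with their list. In both series the mean of hypothalamic genes was highest in fraction 6, and those of thalamic, choroid plexus and ependymal genes in fraction 4. Those of dopamine and serotonin neuron genes were highest in fraction 5, of cortical and Purkinje cell genes in fraction 2 and of hippocampal genes in fraction 3. Other lists parted: granule cell genes peaked in fraction 4 on the left and fraction 2 on the right, striatal genes in fractions 5 and 4, hindbrain genes in fractions 5 and 4, olfactory bulb genes in fractions 3 and 4, and meningeal and blood genes in fraction 1 on the left and fraction 7 on the right. The largest differences by adjusted p were Mreg, 4.60-fold higher in fraction 1 than in fraction 7 on the right and 1.85-fold higher in fraction 4 than in fraction 1 on the left, and Slc22a8, an organic anion transporter, 4.17-fold higher in fraction 7 than in fraction 1 on the right and 2.41-fold higher in fraction 1 than in fraction 4 on the left. Ntn3, a netrin, Cyp4f15 and Hamp2 followed, all 5 at an adjusted p of 0.00519.

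Position changed 4334 probes in the left oblique series (2964 higher) and 17190 in the right (10212 higher), and 8713 probes differed between their curves (4534 with the higher slope on the left, limma). The left count was 297, 2064, 2655, 1299 and 2207 without left fraction 1, 2, 4, 6 and 7, and 1556 of 2820 were higher with quantile normalization. Without right fraction 1 the right count was 2673 and the difference 400; the difference was also 15330 without right fraction 2, 4053 without left fraction 6 and 3039 without left fraction 7, and 2520 with the right numbers reversed. Normexp gave 11079 of 27184 higher on the right and 1938 of 4707 for the difference, and fits of the oblique series alone called 0 on the right (9459 unadjusted) and 0 for the difference (11040 unadjusted) in limma. Across all probes, fractions of the same number correlated at a mean r of 0.11 and fractions of opposite number at 0.16, and 1 of 7 left fractions was best matched by the same right number (exact permutation over all orders of 7 fractions, p = 0.297). Which of the 2 was higher depended on the processing. The same-number r was the higher with normexp (0.28 against 0.22, p = 0.106), with probes well above background on all 42 arrays (0.23 against 0.11, p = 0.102) and with Spearman correlation (0.17 against 0.14, p = 0.184), all by exact permutation. It was the lower with quantile normalization (0.08 against 0.15, p = 0.349) and no filter (0.09 against 0.15, p = 0.319), so these values do not settle the direction. The closest match was left fraction 7 with right fraction 1 (r = 0.818). Left fractions 7 and 6 had the lowest 75th percentiles of signal in their series (234 and 239), as did right fraction 1 (121). Left fractions 7 and 6 nevertheless had the highest shares of probes well above background in their series (60.7% and 59.4%). Right fraction 1 had 55.3%. Whether the low 75th percentile made this match was not tested.

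**Figure D2:**
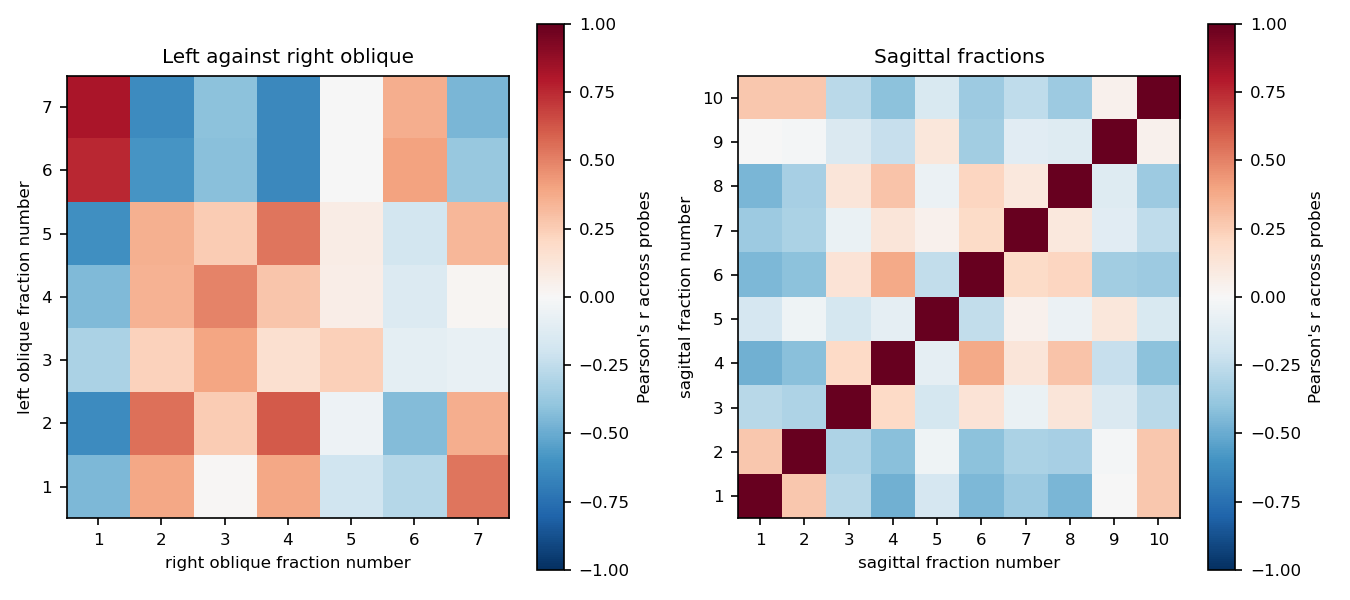
Pearson's r across probes between each of the 7 left oblique fractions (mouse 3, y axis) and each of the 7 right oblique fractions (mouse 4, x axis), and among the 10 sagittal fractions (mouse 5, both axes), with values centred per probe within a series. Left fractions 6 and 7 match right fraction 1 best (0.757 and 0.818), and sagittal pairs at equal distance by number from the middle between fractions 5 and 6 average 0.05. The oblique arrays of this best match had the lowest 75th percentiles of signal of their series, but the left ones had the highest shares of probes well above background.

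Coherence, the mean pairwise correlation of a list's genes over the fractions of 1 mouse, gave 1 value per animal. Genes of some lists varied together in every brain: the means over 5 mice were 0.921 ± 0.0589 for blood, 0.875 ± 0.0671 for Purkinje cells, 0.829 ± 0.0410 for choroid plexus, 0.797 ± 0.0584 for hindbrain and 0.762 ± 0.0952 for olfactory bulb genes (SD, n = 5). Oligodendrocytes (0.678 ± 0.149), granule cells (0.661 ± 0.0780), striatum (0.571 ± 0.137), dopamine neurons (0.506 ± 0.140), hypothalamus (0.490 ± 0.152) and thalamus (0.451 ± 0.0392) completed the 11 of 26 lists that lay above the 95th percentile of 10000 matched random lists in all 5 mice. In 4 of 5 mice this held for microglia (0.672 ± 0.118), meninges (0.684 ± 0.142), ependyma (0.624 ± 0.163), pituitary (0.464 ± 0.210), serotonin neurons (0.366 ± 0.267), cortex (0.311 ± 0.161) and hippocampus (0.163 ± 0.0334). It held in 3 mice for GABA neurons (0.765 ± 0.266), respiratory chain (0.451 ± 0.133), immediate early genes (0.397 ± 0.276), huntingtin partners (0.348 ± 0.135) and polyglutamine disease genes (0.340 ± 0.182), and in 1 mouse for endothelial cells (0.333 ± 0.164), astrocytes (0.197 ± 0.226) and skeletal muscle (0.0680 ± 0.166). With 5 mice the two-sided exact sign-flip permutation cannot go below p = 0.0625, the value of 23 of the lists (adjusted p = 0.0707), so no list could pass 0.05. The others were serotonin neurons (p = 0.125), skeletal muscle (p = 0.25) and astrocytes (p = 0.438), also by exact permutation.

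The striatum is the region most affected in Huntington disease, and genes that shared its profile in all 5 brains were sought. Among 17161 genes, 9 followed the mean of the striatum list with a correlation over fractions of at least 0.7 in every mouse. Members of the list were Rgs9, a regulator of G protein signalling (r 0.957 to 0.992), Drd1 (0.828 to 0.976), Adora2a (0.820 to 0.990), Tac1 (0.855 to 0.968) and Gng7, a G protein subunit (0.822 to 0.975). Outside the list were Serpina9, a protease inhibitor (0.911 to 0.990), Rarb, a retinoic acid receptor (0.864 to 0.980), Lrrc10b (0.843 to 0.967) and Ankrd63 (0.739 to 0.985).

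**Figure D3:**
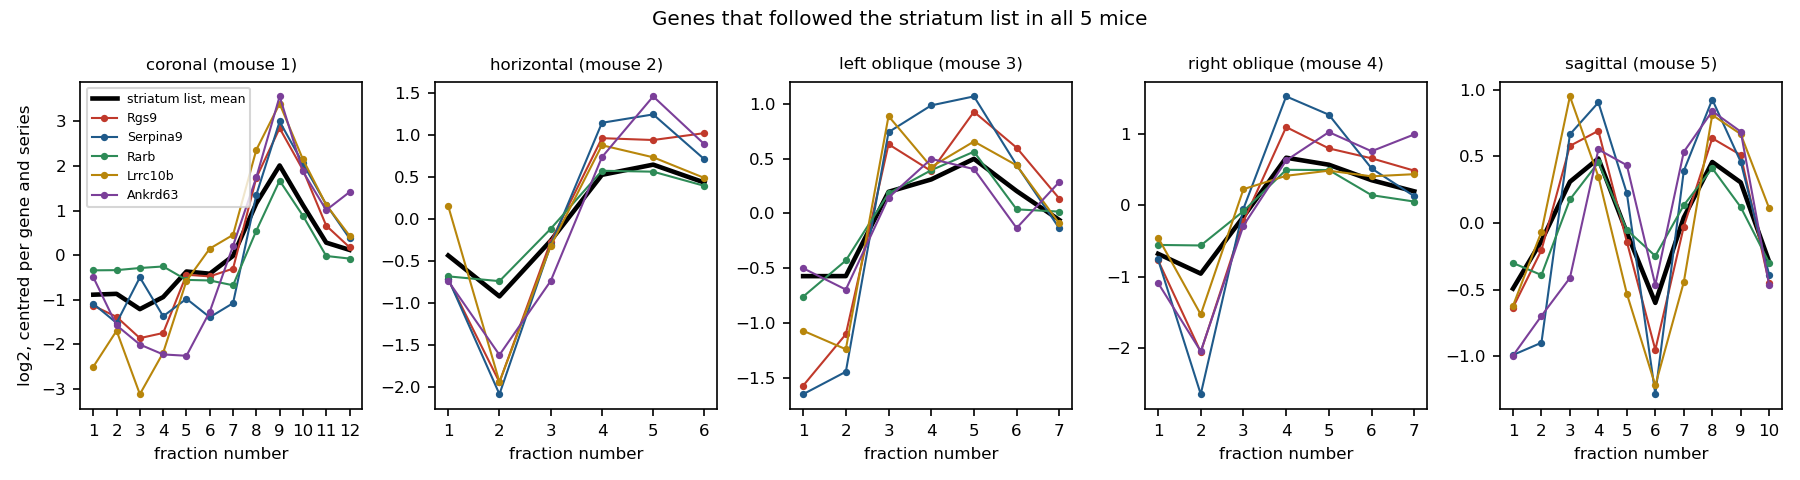
Log2 signal of Rgs9, Serpina9, Rarb, Lrrc10b and Ankrd63 (coloured lines, centred per gene and series) and the mean of the 20 striatum list genes (black) against fraction number in the 5 mice, with a y scale of its own in each panel. All 5 genes rise and fall with the list, with a lowest correlation of 0.739, that of Ankrd63 in mouse 5.

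Of the next genes by mean correlation outside the list, Slc35d3 had its lowest r of 0.667 in mouse 5, Inf2 0.686 in mouse 3, Gdnf, a growth factor of dopamine neurons, 0.624 and Isl1 0.470 in mouse 5, while Musk (−0.117) and Cpne5 (−0.170) did not follow the list in mouse 3. The list members Ptpn5, Adcy5 and Pde1b, which carry dopamine signals in striatal neurons, were at r −0.03, −0.16 and 0.12 in mouse 3 but between 0.713 and 0.936 in the other mice, and Drd2 was at 0.17 in mouse 5. In limma 58 genes passed the adjusted threshold before the minimum of 0.7 was applied. Without mouse 3 the count was 24 and without mouse 5 it was 26, in both cases with all 9 genes kept. Normexp kept 7 of them, without Lrrc10b and Ankrd63, and Spearman correlation 6, without Tac1, Gng7 and Rarb. With probes well above background on all 42 arrays 5 stayed: Tac1, Gng7, Rgs9, Rarb and Serpina9. Ankrd63 was also lost with quantile normalization, without the end fractions and without the 3 arrays of lowest signal. It was not well above background in part of the fractions. Rgs9 and Serpina9 stayed in every setting. Fractions of a brain are not independent samples, so r describes a shared profile.

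A last comparison asked which genes set 1 mouse apart from the other 4 in every fraction. Sim2, a transcription factor gene, was at least 14.5-fold higher in mouse 5, at −0.60 ± 0.38 log2 (SD, 10 fractions) against −5.23 ± 0.14 (SD, n = 4 mice), and was well above background on 10 of 10 arrays there and on 3 of 32 elsewhere. Pop4, a subunit of ribonuclease P, was 6.85-fold higher in mouse 4 (2.97 ± 0.30 against 0.20 ± 0.14). Pttg1, the securin that restrains sister chromatid separation, was 16.4-fold lower in mouse 3 (−0.21 ± 0.42 against 3.82 ± 0.45). H2-D1, a class I histocompatibility gene, was 9.77-fold lower in mouse 5, and Serpina1e, a protease inhibitor gene of a family of near-identical copies, was about 8.61-fold lower in mouse 1, where it was well above background on only 7 of 12 arrays, so this fold is less certain than the others. Zfp874a in mouse 2 (at least 11.4-fold), both Tescl probes in mouse 4 (at least 8.71- and 5.65-fold) and Apoa2, an apolipoprotein, in mouse 5 (at least 4.35-fold) were lower and not well above background on any array of that mouse. Second probes of Sim2 and Apoa2 barely moved, by 0.42 and −0.21 log2, while those of Serpina1e and Pttg1 differed by −1.10 and −2.48 and the 2 Tescl probes by −4.12 and −3.34. Zfp874a, Pop4 and H2-D1 had no second tested probe. In limma 12 probes met the rule, 2 higher and 10 lower, 3 of them without a gene name. Mouse, plane and mostly slide coincide; the count was 3 with normexp and 6 with 1 probe per gene.

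**Figure D4:**
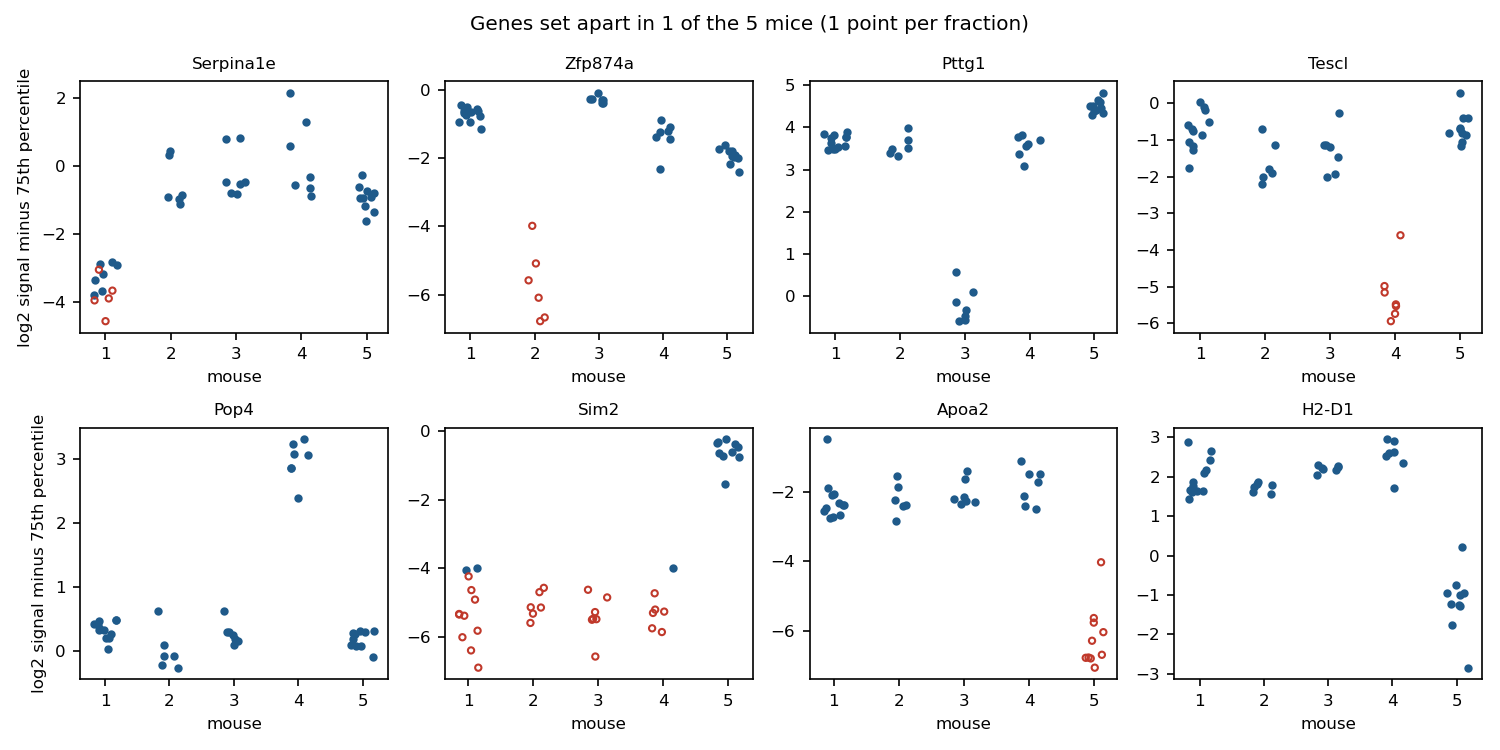
Log2 signal minus the array's 75th percentile for 8 genes that set 1 mouse apart, 1 point per fraction, by mouse; open points are not well above background. Pttg1 lies at −0.21 on average in mouse 3 and at 3.82 in the others, and Sim2 at −0.60 in mouse 5 and −5.23 in the others.

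Immediate early genes also differed in level between mice, a comparison chosen after its values were seen. Relative to the mean of the 5 mice the 10 genes averaged 0.58 ± 0.21 log2 in mouse 3 and 0.32 ± 0.23 in mouse 4 (SD of genes), with 10 of 10 genes higher in each. They averaged −0.40 ± 0.24 in mouse 1 and −0.58 ± 0.20 in mouse 5, with 0 of 10 higher in each, and 0.08 ± 0.23 in mouse 2. Fos stood at 0.87 in mouse 3 and −0.86 in mouse 5, and Egr2 at 0.95 and −0.45. Haemoglobin and other blood genes averaged 0.85 ± 0.25 in mouse 4 and −0.65 ± 0.12 in mouse 5.

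**Figure D5:**
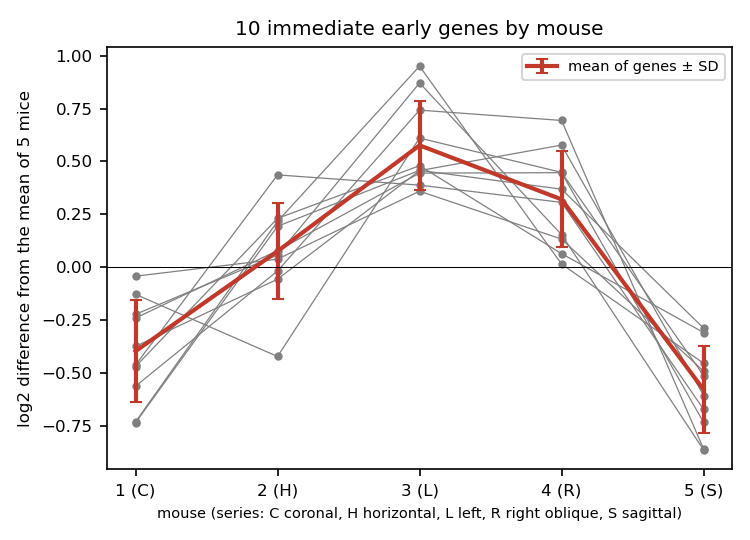
Log2 difference of each of 10 immediate early genes (grey lines) from the mean of 5 mice, by mouse; the red line is the mean of the genes and its bars their SD. The mean runs from −0.58 in mouse 5 to 0.58 in mouse 3.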

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

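All tests in this part were chosen after the results were seen, except the 4 on genes that set a mouse apart, and the limit of 10 placed genes in the last of those was also set afterwards.

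Counts that rest on end fractions were the first pattern weighed, since the 3 arrays of lowest signal are end fractions, and scaling by the 75th percentile could lift dim probes on them. Of all tested probes, 2.12% on horizontal and 3.83% on sagittal fraction 1 rose beyond the 95th percentile of probes never well above background. Such a lift may thus account for called probes that were higher there, 6483 in horizontal position and 4787 in sagittal distance. It does not cover the called probes that were lower there, 6976 and 3916. On right oblique fraction 1 the share was 17.5%, which excludes a lift as the whole cause. The loss of positions could also end calls. Calls without 2 inner fractions were set against calls without both ends. They were at least 26.4 times as many in horizontal position, right oblique position and the oblique difference, and 4.96 times in sagittal distance. This excludes the number of lost positions as the sole cause there. In left oblique position they were only 0.769 times as many, where it stays open. End positions weigh more in a fitted curve than inner ones, so the loss of that weight was not separated and stays open. The ends of a brain also differ from its middle in tissue, and no biological explanation was tested.

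Genes that set a mouse apart were the second pattern. Of the real grouping of the arrays and 100 random ones, 1 reached 12 probes, the real one, with 0 as the highest other. Random groups mix arrays of several mice, so a low count is built into them, and chance differences between single animals cannot be told apart from this and stay open. For the 5 probes of mice 2 and 5 the difference on the slide they share was 0.971 of that over all arrays. The rule asked for a gap of at least 1 log2 in every fraction, also on that slide. A difference there was therefore set by the selection and is no independent test of a slide effect. The ratio shows only that the difference was about as large within that slide as over all arrays. A variant under a probe may account for some genes, since other probes of 5 genes moved by a median of 0.354 of the called probe, which leaves it open, and those of Sim2 and Apoa2 by only 0.0910 and 0.0515. Both Tescl probes were called ones, so their match was set by the selection. Zfp874a, Pop4 and H2-D1 had no other tested probe. A test of linked blocks gave p = 1 with 2 genes placed and cannot tell either.

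Immediate early genes between mice were the third pattern. More cortex in the fractions of mouse 3 could raise them, but the cortex list differed from mouse 5 by only 0.165 of their difference. This argues against it for these 2 mice. Other pairs were not compared in this way. Across the 5 mice the cortex list had a range of 0.602 log2, so cortex content stays open for the other mice. A spread that other lists share stays open, since the genes were picked for this spread of 1.15 log2 (permutation p = 0.0005 over 10000 random lists, highest 1.27) and the olfactory bulb list had 1.17 and the blood list more. Mean levels over fractions also depend on the plane of cutting, which differed between all mice. A slide effect between mice 2 and 5 may account for part, with 0.777 of the difference left on the shared slide, which cannot tell. Mice 3 and 4 were scanned on the same 2 days as each other, and no other mouse was scanned on those days. The handling of the mice is not in the labels, so no biological explanation was tested.

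Of the real order of the fractions and 100 drawn at random, the orders with as many calls as the real one, itself included, numbered 1 for coronal position (12937, highest other 2451), 1 for the coronal slope (10374, 4440), 1 for horizontal position (13459, 5945) and 3 for the horizontal slope (4964, 6736). They numbered 1 for sagittal distance (8703, 2271), 1 for its slope (9448, 2023), 3 for asymmetry (41, 2609), 1 for left oblique position (4334, 84), 1 for right oblique position (17190, 5721), 1 for the oblique difference and 1 for co-variation (9, 0). For the tests of position and of the oblique difference at 1, none of the 100 drawn orders reached the real count. Each draw shuffled all 5 series at once, so the residual spread that all tests share changed as well. The counts thus speak to the orders of the 5 series together, and cannot exclude a chance order of 1 named series. For co-variation a shuffled profile had to reach 0.7 in all 5 mice. A count of 0 was thus nearly built in, and that test cannot tell. For the horizontal slope and asymmetry 2 of 100 random orders gave at least as many calls, with up to 2609 against 41 for asymmetry. What raised the counts in those orders was not tested, and for these 2 tests chance order is not taken as excluded for the 5 series together either.

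Of 60 groups tested, 8 held a value far from the others, where chance gives about 1 in 20. Most groups were a list's values over 5 mice, and the rest were array signal measures over the fractions of 1 series. All 8 were lists over 5 mice. Coherence was low for serotonin neurons in mouse 2 (−0.100), Purkinje cells in mouse 5 (0.760) and GABA neurons in mouse 1 (0.304), and high for immediate early genes in mouse 3 (0.873). Mean levels were low for olfactory bulb (−0.86) and granule cell genes (−0.60) in mouse 1, and high for serotonin neurons in mouse 2 (0.28) and oligodendrocytes in mouse 1 (0.43). Such a level is a mean of log2 values over fractions, so it depends on how a plane spreads a region over them. The olfactory bulb list reached 4.48 log2 above its series mean in coronal fraction 12, and at most 1.465 in the other planes. These levels therefore cannot be read as differences between mice apart from the plane. The oblique curves differed for 8713 probes, a difference between groups with the test of the difference itself (highest other order 5621).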

How the results depend on the processing

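Asymmetry counts depended most on the processing, with 1 of 14 alternatives within 1.5 times, and horizontal, sagittal distance, left and right oblique and mouse-specific counts also moved widely. The coronal slope count ran from 5960 to 12130 over 13 alternatives, 11 of them within 1.5 times, and coherent lists from 5 to 15 over 14, 13 of them within, while co-varying genes ran from 2 to 31 over 18, 13 of them within. The same-number oblique r ran from 0.08 with quantile normalization to 0.28 with normexp, below or above the opposite-number r. No paired analysis was possible because replicate numbers are positions in different planes of different mice. Signal over background limits dim probes, but the 3 arrays of lowest signal were not all the most limited. Right oblique fraction 1 had 55.3% of probes well above background and right oblique fraction 7 had 47.6%. Except where the construction shows it, the cause was not tested.

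With normexp the counts were 24328 for coronal position, 28010 and 21182 for horizontal position and slope, 16536 and 20499 for sagittal distance and its slope, 13938 for asymmetry, 27184 for right oblique position, 4707 for the oblique difference and 3 for mouse-specific probes. It turned the slopes of Actn3 (horizontal, −0.13), C1ql2 (sagittal distance, 0.0229) and Zfp773, Zfp971, Dusp18 and Myh4 (asymmetry, −0.0538, −0.0487, −0.0268 and −0.0876); the cause was not tested. Quantile normalization gave 2820 for left oblique position and 2 for asymmetry and turned Cox6a1 (horizontal, 0.0102) and Ndufb8 (sagittal distance, −0.0232); the cause was not tested. With no filter the counts were 22506 and 8961 for horizontal position and slope, 13214 and 15511 for sagittal distance and its slope and 5875 for asymmetry. With probes well above background on all 42 arrays they were 2595 for left oblique position, 1029 for asymmetry, 5 coherent lists, 3 mouse-specific probes, 5 co-varying genes and a mirror r of 0.33 (exact permutation p = 0.0333).

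A fit of the tested series alone has fewer residual degrees of freedom by construction and gave 6459 for coronal position, 2517 for left oblique position and, by limma, 0 for the horizontal slope (14204 unadjusted), right oblique position (9459 unadjusted), the oblique difference (11040 unadjusted) and asymmetry (7012 unadjusted). A polynomial 1 degree lower gave 8550 for coronal position, 345 for horizontal position and 345 for its slope, 1659 and 2537 for left and right oblique position, 5378 for sagittal distance and 5378 for its slope, and 2 for asymmetry. With 1 probe per gene fewer were tested by construction (17161), with 7575 and 6033 for coronal position and slope, 7576 for horizontal position, 5231 and 5625 for sagittal distance and its slope, 26 for asymmetry, 2592 and 9469 for left and right oblique position, 4603 for the oblique difference and 6 mouse-specific probes. Slides as a random block gave 5960 for the coronal slope and 1 for asymmetry, and leaving out the second scanner 25 for asymmetry. Reversed right numbers gave 2520 for the oblique difference.

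Without the end fractions, a setting with fewer arrays by construction, the counts were 109 and 119 for horizontal position and slope, 976 and 1516 for sagittal distance and its slope, 1 for asymmetry, 970 and 365 for left and right oblique position and 2 for the oblique difference, and Gad1 (coronal, −0.00476) and Cbln3 (sagittal distance, 0.00571) turned. Without the 3 arrays of lowest signal they were 699 and 178, 4076 and 5548, 2, 8062 and 3102, and 416, in the same order. Without 2 inner fractions they were 6964 and 2022 for horizontal position and slope, 4843 for sagittal distance, 1 for asymmetry and 746 and 9630 for left and right oblique position. Leaving out 1 mouse gave 9 to 26 co-varying genes and 11 to 14 coherent lists. A lowest correlation of 0.5 or 0.9 gave 31 or 2 co-varying genes, and a gap of 0.5 or 2 log2 gave 30 or 2 mouse-specific probes. With the sagittal middle at fraction 6, limma called 0 for asymmetry (1302 unadjusted).

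Of 30 list calls 0 stayed with an estimated correlation (lowest adjusted p = 0.305), 22 with probes well above background on all 42 arrays, 23 with normexp, 24 without the 3 arrays of lowest signal, 25 with quantile normalization, 25 without the end fractions, 26 with no filter, and 29 each with the deposited table, without the second scanner and with the sagittal middle at fraction 6. A list with too few genes left for the test in a setting was counted as not kept. Of those lost, 1, 1 and 2 lay in the opposite direction with normexp, without the 3 arrays and with quantile normalization.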

Other observations

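The tests in this part were chosen after the results were seen.

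Other cell groups had profiles of their own that the report's slopes do not show. Choroid plexus genes peaked in coronal fraction 3 (9 of 11 genes, 1.94 ± 0.32 log2 above the series mean, SD of genes) and horizontal fraction 4 (10 of 11), and Ttr, which carries thyroid hormone, was 121-fold higher in coronal fraction 2 than in fraction 1. Ependymal genes peaked in coronal fraction 8 and sagittal fraction 6, and meningeal genes in horizontal fraction 1 (7 of 8). The mean of pituitary genes was highest in the fractions that held the hypothalamic peak or its neighbour in all 5 mice, fraction 6 of the coronal, horizontal, left oblique and sagittal series and fraction 7 of the right oblique series.

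The profile search was repeated with the other lists. Genes at a correlation of at least 0.7 in every mouse numbered 798 for huntingtin partners, 536 for polyglutamine disease genes, 240 for the respiratory chain, 198 for oligodendrocytes, 174 for granule cells, 152 for microglia, 77 for Purkinje cells, 44 for hindbrain, 39 for blood, 31 for cortex, 29 for choroid plexus, 27 for meninges, 25 for olfactory bulb, 21 for ependyma, 18 for GABA neurons and 18 for immediate early genes. The other lists had 10 for endothelial cells, 9 for striatum, 8 for thalamus, 7 for hypothalamus, 6 for dopamine neurons, 2 for hippocampus, 2 for serotonin neurons, 1 for pituitary and, by limma, 0 for skeletal muscle (2096 past the adjusted threshold alone) and 0 for astrocytes (14 alone). Only 1 of 12 huntingtin partners and 1 of 9 polyglutamine disease genes were themselves among the genes counted for their list. For these 2 lists 8666 and 7177 of 17161 genes passed the adjusted threshold alone. Their counts therefore do not show a profile of the lists' own.

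Both oblique series may start at the same pole of the brain. Over 132 genes of the region lists, same-number fractions correlated at a mean r of 0.59 and opposite ones at −0.14, and of all orders of 7 fractions none did better (exact permutation p = 0.000198, the smallest possible), while reversed numbers gave p = 0.771. All 7 left fractions were matched best within 1 fraction of the same right number. These genes were chosen after the peaks of their lists were seen. Of the 13 lists, 9 peaked in the same fraction number in both series and 12 within 1 fraction. The p-value was thus partly set by that choice and is no independent test. Meningeal and blood genes, which peaked in fraction 1 on the left and fraction 7 on the right, were not among them. Over all probes, as the report gives, which match was closer depended on the processing, so the start stays open there.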
